A study of Mus musculus with 24 samples.

How the data were processed

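The deposited data are raw counts of 3′ tags per gene in the left brain hemisphere of 24 mice. Per the labels, 3-month-old wild type and Nox2 knockout mice received an intraperitoneal injection of 100 µl of either lipopolysaccharide (LPS, a component of the outer membrane of gram-negative bacteria) or phosphate-buffered saline (PBS) on each of 4 days. The LPS dose was 1 µg per g body weight per day. Each of the 4 groups held 6 animals, and every library carries the same strain label, C57BL/6J. RNA was isolated from the homogenised hemisphere, and 100 ng of total RNA entered the QuantSeq 3′ mRNA-Seq preparation, per the labels' protocols. This kit counts tags near the 3′ end of each polyadenylated transcript, so a gene's length has little bearing on its count.

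The authors made these counts before deposit. Per the submitters' processing notes, the tools were bcl2fastq, STAR 2.7.3a, featureCounts of Subread 2.0.0, R 3.6.1 and DESeq2 1.26.0, with the mouse build mm10 (GRCm38). The annotation release, the strand setting, the treatment of reads with several matches and any removal of PCR duplicates are not given in the sources used here. Reads shared between near-identical genes, such as the globin genes or the major histocompatibility genes, can have been split or dropped, so the values of single members of such families are uncertain. Without a stated strand setting, overlapping and antisense genes cannot be told apart either. The deposited table holds whole-number counts for 55421 Ensembl gene identifiers. Of these, 55154 come with a symbol, and all 55154 have coordinates in GENCODE M21 for GRCm38, used here for positions. The other 267 identifiers have no symbol, were kept as genes and took 0.00933 to 0.022% of a library's counts.

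Libraries held 2.34e+06 to 5.26e+06 counts, so 1 count per 1e+06 counts (CPM) stands for 2.34 to 5.26 counts. The reads carry no molecular identifiers in the sources used here, so counting intervals and floors cover counting error only. Where all libraries of a group were at 0 counts, a fold is given as a bound with 3 counts over the group in place of 0. With 1 to 3 counts in a group, the ratio of counts is given with its exact 95% interval.

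All 24 libraries entered a single fit with edgeR 4.0.16 under R 4.3.3, with a mean for each group, TMM normalisation, the quasi-likelihood F test and 20 residual degrees of freedom. The function filterByExpr, with its minimum count of 10, kept 14380 genes. P-values were adjusted by Benjamini-Hochberg over these genes within each of the 5 comparisons, and a gene was called at an adjusted p under 0.05. The comparisons were LPS against PBS in each genotype, knockout against wild type after each injection, and the interaction, which is the LPS change in knockout minus the LPS change in wild type. Errors on log2 fold changes are standard errors (SE) from this fit, and errors on levels are standard deviations (SD, n = 6). The replicate numbers in the labels were not used to match animals.

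Before the data were examined, 41 gene lists with 723 entries were fixed. They cover NADPH oxidase, immune and stress responses, brain and blood cell types, brain regions and signs of RNA quality. Of these entries, 608 were tested. Each list with at least 3 tested genes was set against all other genes with camera from limma 3.58.1, at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. The test was repeated with a correlation estimated for each list, and fry was run beside it. The pituitary list kept 2 tested genes and got no test. Counts of list members called are over all genes tested, and beside them stand counts adjusted over the list alone.

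The rule for named genes was also fixed before the data were examined. It takes Cybb and the tested NADPH oxidase subunits, then for each comparison of 2 groups the 8 genes with the largest rise and the 8 with the largest fall. These genes had to be called and have a mean of at least 2 CPM over the libraries compared. Every library of the first-named group also had to lie on the same side of the other group's mean log2 CPM. Under this rule predicted genes were counted but not named. Some genes that the rule takes, and results that rest on them, are not reported here. For each list it takes the 4 members with the smallest p in wild type, and for lists described under a later comparison the 4 with the smallest p there. Genes named outside this rule are said to have been chosen after their values were seen. Of the genes the rule allows from the lists, the text leaves some out, in part after it was seen that their calls ended when a single library was left out.

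The calls were tested on simulated counts with the means and library sizes of these data and 67 genes changed at each of the sizes given here. At a log2 change of 1, the fit over 14380 genes recovered 92.5% of changed genes for LPS in wild type, 94.0% for LPS in knockout, 89.6% for genotype under PBS, 88.1% for genotype under LPS and 76.1% for the interaction. At a log2 change of 0.5 these shares were 70.1, 53.7, 58.2, 70.1 and 41.8%. False calls made up 5.41, 2.94, 4.09, 3.93 and 3.33% of calls. With the simulated LPS change in wild type, all 10 shifted lists were called and 0 of 10 unshifted lists. The simulated genes were drawn independently of each other, and these lists were random. The simulation therefore does not test false list calls where the genes of a list are correlated. Nor does it test false gene calls where libraries share structure other than the groups.

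Alternatives fixed before the data were examined were DESeq2's size factors and plain total counts in place of TMM, the DESeq2 1.42.0 Wald test in place of edgeR, no filter, a stricter filter (over 1 CPM in at least 6 libraries), the replicate number as a block, only the libraries of the groups compared, each library left out in turn, and a log2 fold change over 1 as an added threshold. Added after seeing the data were fits without replicates 1 and 2 of the wild type LPS group, with a score of olfactory bulb genes as covariate, and without the mitochondrial genes and Gm42418, plus the NADPH oxidase list test without Cybb. No library and no column was left out of the comparisons described first.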

Results

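Gene expression was measured by 3′ tag sequencing of the left brain hemisphere in 4 groups of 6 mice, wild type or Nox2 knockout and injected with PBS or LPS. The study's title concerns gp91phox, the catalytic subunit of the phagocyte NADPH oxidase, after repeated systemic exposure to LPS. The libraries held 2.34e+06 to 5.26e+06 counts each. Group means in units of 1e+06 counts were 4.12 ± 1.06 (SD, n = 6) in wild type PBS, 3.73 ± 0.467 in wild type LPS, 3.79 ± 0.52 in knockout PBS and 3.74 ± 0.76 in knockout LPS. Two-sided exact permutation tests over the 924 splits found no difference in depth larger than the spread between animals, with p from 0.435 to 0.978 in the 4 comparisons. Gm42418, a predicted gene that overlaps ribosomal RNA sequence, took 7.39 to 9.09% of the counts in a library. The mitochondrial ribosomal RNA genes took 3.39 to 5.39%, with the highest shares, 5.07 and 5.39%, in replicates 1 and 2 of the wild type LPS group. These 2 libraries also differed from replicates 3 to 6 of their group in other values. Chi-square per degree of freedom, which grows with the difference between 2 libraries, was 1.91 between them and 3.08 to 5.16 against the others. Among replicates 3 to 6 it was 1.77 to 3.32. Cybb stood at 15.7 CPM in each, against 23.7 to 34.0 CPM, and S100a5 at 0 counts, against 30 to 37. Per the labels each library came from a separate animal, and no libraries of a group were alike within counting noise.

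Cybb (ENSMUSG00000015340, chromosome X, 9435252 to 9487771, minus strand, GRCm38) encodes gp91phox, also called Nox2, and is the gene targeted in the knockout. Its level was higher in the libraries labelled knockout than in those labelled wild type. Wild type libraries held 1.49 ± 0.653 CPM (SD, n = 6) after PBS and 24.7 ± 8.06 CPM after LPS, and libraries labelled knockout held 67.8 ± 5.18 and 72.0 ± 4.04 CPM. In counts, the wild type libraries ranged from 2 to 10 after PBS and from 48 to 140 after LPS, against 207 to 288 and 173 to 322 in the libraries labelled knockout. LPS raised Cybb in wild type by 3.99 ± 0.22 on the log2 scale (SE, edgeR adjusted p = 2.98e-19), whereas the LPS change in the libraries labelled knockout was 0.09 ± 0.10 (adjusted p = 0.68). The tags lie at the 3′ end of the transcript and the labels do not give the disrupted part of the gene, so these counts do not check the genotype labels. Every direction between genotypes given here rests on the labels, and knockout means the libraries labelled so.

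**Figure D1:**
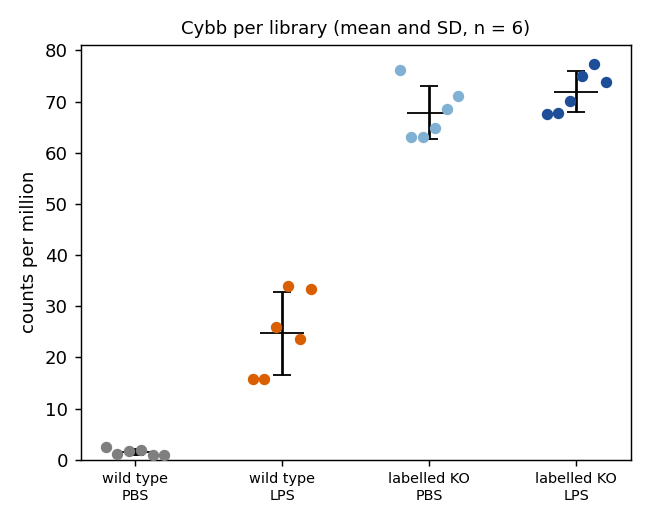
CPM of Cybb in each of the 24 libraries, by group. Points are libraries, and bars show the mean and SD (n = 6). Cybb averaged 1.49 CPM in wild type PBS, 24.7 CPM in wild type LPS and 67.8 and 72.0 CPM in the libraries labelled knockout.

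LPS in wild type mice raised a broad set of inflammatory genes in the hemisphere. Among named genes with more than 3 counts over the PBS libraries, Saa3, a serum amyloid A protein of the acute phase response, rose most. It rose by 9.24 ± 0.35 on the log2 scale, and Lcn2, the siderophore-binding lipocalin 2, by 7.25 ± 0.32. Cd5l, Gzma and Marco, with 0 to 3 counts there, are given below as ratios or bounds. The chemokine Ccl5 rose by 6.29 ± 0.39, the Fc receptor gene Fcgr4 by 5.56 ± 0.47 and haptoglobin, Hp, by 5.46 ± 0.54. The largest falls were in the globin genes of red blood cells, Hba-a1 at -3.95 ± 0.98 and Hbb-bs at -3.46 ± 0.69, and in Gkn3, a gastrokine gene, at -2.51 ± 0.37. By the rule that named them, each of these genes lay on the stated side of the PBS mean in all 6 LPS libraries.

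Complement and phagocytosis genes rose as a group in wild type. Of 25 tested members, 22 were higher and 0 lower, with a median log2 fold change of 2.21 (camera adjusted p = 1.43e-84). Adjusted over the list alone, 22 were higher and 1 lower. The C1q chains C1qa, C1qb and C1qc rose by 2.24 ± 0.08, 1.78 ± 0.08 and 2.03 ± 0.09, and C4b, the fourth complement component, by 2.90 ± 0.12. Marco, a scavenger receptor of macrophages, went from 3 counts over the PBS libraries to 355 over the LPS libraries, a ratio of 130 (exact 95% interval 44.2 to 635). Of 18 lysosome genes, 17 were higher and 0 lower, over all genes and over the list alone, among them the cathepsins Ctss (1.67 ± 0.07) and Ctsd (1.04 ± 0.06) and progranulin, Grn (1.57 ± 0.08). Activated microglia genes showed 20 of 21 higher, with 20 also over the list alone, including Cd52 (3.48 ± 0.19) and B2m (1.76 ± 0.08). Homeostatic microglia genes rose as a list but not in every member, with 12 of 19 higher and 2 lower by either adjustment. Their median was 0.736 (camera adjusted p = 2.9e-11, adjusted p = 0.000252 with an estimated correlation). The receptors Csf1r and Cx3cr1 were among those that rose, by 1.27 ± 0.09 and 1.25 ± 0.09.

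The subunits of the NADPH oxidase rose with the microglial and myeloid genes. Of 8 tested subunits, 5 were higher and 0 lower (7 and 0 over the list alone), with a median of 1.89. Besides Cybb these were Cyba (2.06 ± 0.15), Ncf1 (1.72 ± 0.16), Ncf4 (2.44 ± 0.38) and Rac2 (3.72 ± 0.26), while Rac1 stood at 0.08 ± 0.04 (adjusted p = 0.199). Toll-like receptor and NF-kB pathway genes showed 20 of 24 higher and 0 lower (22 and 0 over the list alone), with Cd14, the LPS co-receptor, up by 2.66 ± 0.23 and the adhesion molecule Icam1 by 3.74 ± 0.32. Cytokines and chemokines showed 9 of 14 higher and 1 lower (11 and 2 over the list alone), including Cxcl16 (2.71 ± 0.26) and Cxcl1, which had 131 counts after LPS against 3 after PBS, a ratio of 48.1 (16.1 to 236). Type I interferon genes had 13 of 23 higher and 0 lower (16 and 0 over the list alone), with Ifitm3 up by 2.17 ± 0.11 and Lgals3bp by 1.66 ± 0.15. Antigen presentation genes had 17 of 24 higher and 0 lower (23 and 0 over the list alone), with the class I genes H2-K1 and H2-D1 up by 2.27 ± 0.13 and 1.92 ± 0.10.

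Genes of reactive astrocytes and of the vessel wall also rose in wild type. Of 11 shared astrocyte reactivity genes 10 were higher, as were 10 of 11 A1 genes and 3 of 6 A2 genes (11, 11 and 4 over the list alone), and none was lower. Gfap, the intermediate filament of astrocytes, rose by 2.26 ± 0.10, the protease inhibitor Serpina3n by 4.40 ± 0.23 and complement C3 by 4.61 ± 0.23. Endothelial identity and barrier genes had 16 of 19 higher and 0 lower by either adjustment, with the tight junction gene Cldn5 up by 2.17 ± 0.13, Pecam1 by 1.74 ± 0.11 and Esam by 1.35 ± 0.09. Endothelial activation genes had 13 of 16 higher and 0 lower (13 and 1 over the list alone), with von Willebrand factor, Vwf, up by 2.94 ± 0.11, Lrg1 by 3.63 ± 0.22 and Vcam1 by 1.28 ± 0.10. Pericyte and smooth muscle genes had 8 of 10 higher (9 over the list alone), with a median of 0.601. Antioxidant genes had 10 of 21 higher and 1 lower (12 and 1 over the list alone), among them glutathione peroxidase 3, Gpx3 (2.37 ± 0.13), Prdx6 (0.68 ± 0.06) and haem oxygenase 1, Hmox1 (1.82 ± 0.25). Apoptosis and cell death genes had 4 of 16 higher (7 over the list alone), with a median of 0.301 (camera adjusted p = 0.0242).

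Genes of the blood cell lists moved in both directions in wild type. All 9 tested neutrophil genes were higher, with a median of 4.50, including S100a8 (4.73 ± 0.38) and S100a9 (4.30 ± 0.37), the subunits of calprotectin. Monocyte and border macrophage genes had 10 of 11 higher (11 over the list alone), with Lyz2 up by 3.86 ± 0.16, Ms4a6c by 3.98 ± 0.21 and the chemokine receptor Ccr2 by 3.90 ± 0.45. Gzma, a granule protease of cytotoxic lymphocytes, had 96 counts after LPS and 0 after PBS, at least 35.2-fold higher with 3 counts over the group as floor, and Cd5l, a protein secreted by macrophages, was at least 48.4-fold higher on the same floor. The lymphocyte list of 3 genes, however, had a camera adjusted p of 0.173. Of 5 erythrocyte genes 4 were lower, with a median of -3.16. Whether these genes changed in blood cells or in cells of the tissue was not tested.

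Neuronal genes fell by small amounts in wild type. Of 33 synapse and neurotransmission genes 14 were lower and 1 higher (15 and 1 over the list alone), with a median of -0.144 (camera adjusted p = 5.06e-05). Snap25, a part of the vesicle fusion machinery, fell by 0.36 ± 0.06, Stx1a by 0.40 ± 0.07 and Syt1 by 0.19 ± 0.04. Oligodendrocyte and myelin genes went both ways, with 4 of 19 higher and 7 lower by either adjustment. Cldn11, a claudin of myelin, rose by 0.61 ± 0.05 and the small heat shock protein gene Cryab fell by 0.69 ± 0.07 (camera adjusted p of the list 0.636). Bcas1, from the oligodendrocyte precursor list, fell by 0.47 ± 0.05, and that list had 2 of 13 higher and 2 lower (2 and 3 over the list alone, camera adjusted p = 0.105). Of 11 cell cycle genes 4 were higher, among them Cdk1 and Top2a (1.64 ± 0.29), and the list stood at a camera adjusted p of 0.051.

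In total, edgeR called 1572 genes higher and 1024 lower after LPS in wild type, of 14380 tested. With a log2 fold change over 1 as well, the counts were 518 and 14, so most of the falls were small. Of 40 lists tested, camera called 22 higher and 4 lower, and 21 of the 26 calls held with an estimated correlation. The 5 that did not were astrocyte identity and meninges and fibroblast (adjusted p = 0.142 each with an estimated correlation), glucocorticoid response (adjusted p = 0.304), mitochondrially encoded genes (adjusted p = 0.414) and cerebellum (adjusted p = 0.372). These had 6 of 15, 3 of 13, 6 of 20, 1 of 8 and 0 of 13 members higher and 1, 0, 2, 3 and 4 lower. The metallothionein genes Mt1 and Mt2 were among the glucocorticoid response genes that rose, by 1.06 ± 0.05 and 0.82 ± 0.06. Not called were the dopaminergic neuron, immediate early, heat shock, nuclear-encoded oxidative phosphorylation, circadian, choroid plexus, ependyma, striatum, hippocampus and thalamus lists, with camera adjusted p from 0.0659 to 0.719. The genes with the largest falls also included Hba-a2, Hbb-bt, Tnnc1, Ccdc151 and Pkd2l1, by 3.16 ± 0.78, 2.85 ± 0.61, 1.44 ± 0.23, 1.33 ± 0.30 and 1.11 ± 0.31.

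**Figure D2:**
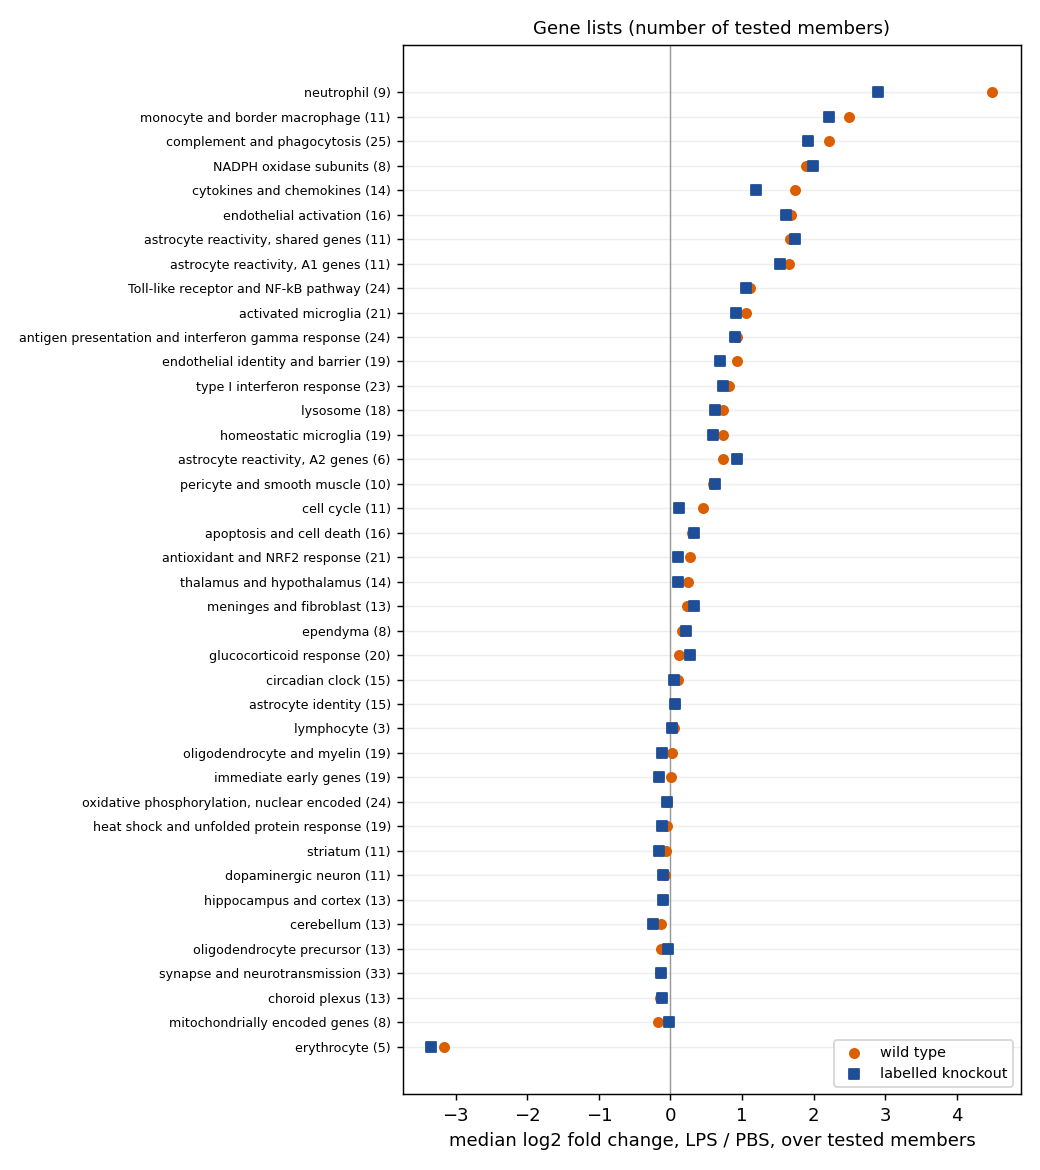
Median log2 fold change, LPS against PBS, over the tested members of each of the 40 lists (number of tested members in brackets), in wild type (circles) and in the libraries labelled knockout (squares). Neutrophil genes had the highest medians, 4.50 and 2.90, and erythrocyte genes the lowest, -3.16 and -3.34.

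LPS in the libraries labelled knockout raised the same kinds of genes. Saa3 rose by 8.16 ± 0.36 on the log2 scale, Ccl5 by 6.65 ± 0.44 and Lcn2 by 6.43 ± 0.33. Marco had 165 counts after LPS against 1 after PBS, a ratio of 167 (exact 95% interval 29.5 to 6630), Cxcl1 146 against 1, a ratio of 148 (26.1 to 5870), and Fcgr4 118 against 2, a ratio of 59.7 (16.2 to 499). The immune receptor genes Clec4a1 and Pirb rose by 4.70 ± 0.41 and 4.53 ± 0.53. The globin genes again fell most, Hba-a2 by 3.55 ± 0.57, Hba-a1 by 3.42 ± 0.61, Hbb-bs by 3.34 ± 0.51 and Hbb-bt by 2.89 ± 0.48, followed by Gkn3 (2.08 ± 0.33 lower), Gucy2g, Bfsp2 and Etv4.

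Of the 25 complement and phagocytosis genes, 21 were higher and 1 lower in the libraries labelled knockout (23 and 1 over the list alone), with a median of 1.92. C1qa rose by 1.97 ± 0.08 and C4b by 2.60 ± 0.13. Lysosome genes had 15 of 18 higher and activated microglia genes 19 of 21, by either adjustment, with Ctss up by 1.93 ± 0.07, Ctsd by 0.65 ± 0.06 and Cd52 by 3.35 ± 0.19. Of the NADPH oxidase subunits 5 of 8 were higher (6 over the list alone), among them Cyba (2.16 ± 0.16), Ncf1 (1.86 ± 0.17), Ncf4 (2.34 ± 0.48) and Rac2 (3.10 ± 0.29). Shared astrocyte reactivity genes had 8 of 11 higher (9 over the list alone), with Gfap up by 1.88 ± 0.10 and Serpina3n by 3.53 ± 0.23. Endothelial identity genes had 14 of 19 higher (17 over the list alone), with Cldn5 up by 1.65 ± 0.13 and Esam by 0.92 ± 0.09, and Vwf of the endothelial activation list rose by 2.65 ± 0.13. All 9 neutrophil and all 11 monocyte genes were higher, with S100a8 up by 3.48 ± 0.39, Lyz2 by 3.35 ± 0.17 and Ccr2 by 2.26 ± 0.45. Synapse genes had 8 of 33 lower and 0 higher (10 and 0 over the list alone), with a median of -0.129. Stx1a fell by 0.36 ± 0.07 and Syt1 by 0.23 ± 0.04, while Snap25 stood at -0.12 ± 0.06 (adjusted p = 0.196).

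With the same test, 1014 genes were called higher and 550 lower in the libraries labelled knockout, 427 and 11 of them with a log2 fold change over 1. Camera called 21 lists higher and 8 lower, and 23 of these 29 calls held with an estimated correlation. Those lost were immediate early genes (adjusted p = 0.296 with an estimated correlation), heat shock (adjusted p = 0.18), nuclear-encoded oxidative phosphorylation (adjusted p = 0.309), striatum (adjusted p = 0.18), cerebellum (adjusted p = 0.164) and hippocampus and cortex (adjusted p = 0.13). The pituitary hormone genes Gh and Pomc were called, at 5.23 ± 1.01 and 3.13 ± 0.71. Yet only 3 of 6 LPS libraries lay above the mean log2 CPM of the PBS libraries for either. Without replicate 4 of the knockout LPS group, which alone held 6460 Gh counts, Gh stood at -0.43 and Pomc at -0.07. The call of Gucy2g, lower by 1.09 ± 0.30, ended without replicate 1 of the knockout LPS group (adjusted p = 0.0537).

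The LPS changes in both genotypes were then set side by side. Of the genes called higher, 855 were shared, against 111 for independent lists, and of those called lower 281 were shared, against 39.2. Only 2 genes were called in opposite directions. Across the 3022 genes called in either genotype, the log2 fold changes had a Pearson r of 0.925 and a Spearman rho of 0.846, and 90.5% had the same sign. Across all 14380 genes, r was 0.847 and rho 0.474. These values are across genes, which are not independent replicates, and the LPS comparisons share no library. The orthogonal slope of the knockout on the wild type changes was 0.859 (jackknife SE over the 24 libraries 0.0539), and 73.6% of the 3022 genes had the larger change in wild type, against 58% of all 14380. This is a description of size, and the 3022 genes hold more calls from wild type (2596) than from knockout (1564), which can favour larger wild type changes among them. The test of single genes is the interaction given last.

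**Figure D3:**
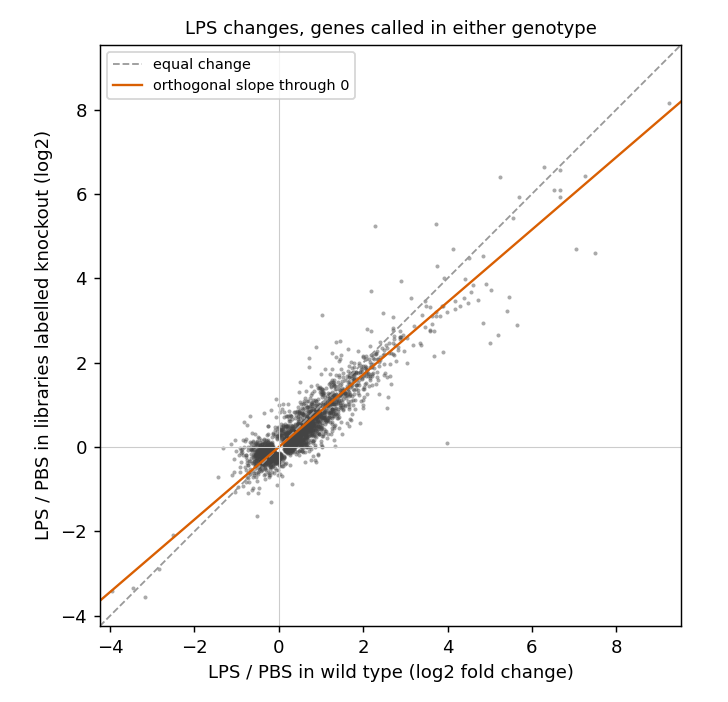
Log2 fold change, LPS against PBS, in wild type (horizontal axis) and in the libraries labelled knockout (vertical axis) for the 3022 genes called in either. The dashed line marks equal changes and the solid line the orthogonal slope through 0 of 0.859. The point near 4 on the horizontal axis and 0 on the vertical axis is Cybb.

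Between genotypes under PBS, few genes differed, and some of them by large amounts. Tmem181b-ps, a pseudogene whose reads can be shared with its near-identical relatives, had 272 counts in the libraries labelled knockout against 1 in wild type, a ratio of 294 (exact 95% interval 52.3 to 11700). Cybb was higher by 5.42 ± 0.18 on the log2 scale, the Y-linked helicase gene Ddx3y by 0.70 ± 0.06 and the clock repressor Nr1d2 by 0.33 ± 0.06. Lower in the libraries labelled knockout were Wdfy1 by 1.78 ± 0.08, Gabra2, a subunit of the GABA-A receptor, by 1.15 ± 0.07, Cdkn1a, the cell cycle inhibitor p21, by 0.82 ± 0.13 and Ndn, the imprinted gene of necdin, by 0.72 ± 0.05.

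S100a5 and Omp, both markers of olfactory sensory neurons, were lower under PBS in the libraries labelled knockout, at -4.17 ± 0.66 and -3.79 ± 0.63. Each had all 6 libraries below the wild type mean, as the rule that named them requires. S100a5 had 266 counts over the wild type PBS libraries and 13 over the knockout PBS libraries. Doc2g and Fabp7 were called at -1.36 ± 0.30 and -0.81 ± 0.18, but each call ended in 8 of the 12 fits with a library left out, with the highest adjusted p (0.408 and 0.192) without replicate 3 of the wild type PBS group. With a score of 11 olfactory bulb genes as covariate, an alternative chosen after the data were seen, the calls of S100a5 at -2.71 (adjusted p = 0.0718), Omp at -2.05 (adjusted p = 0.197), Doc2g (adjusted p = 0.434) and Fabp7 (adjusted p = 0.276) ended. The NADPH oxidase subunits apart from Cybb were not called over all genes, with Ncf4 at -0.77 ± 0.60 (adjusted p = 0.771) and Rac1 at -0.02 ± 0.04 (adjusted p = 0.962). Over the list alone, 1 of 8 subunits was higher and 1 lower.

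In all, 6 genes were called higher and 13 lower under PBS, with 1256 at an unadjusted edgeR p below 0.05. The count moved to 12 higher without replicate 5 of wild type PBS and 15 without replicate 1 of knockout PBS. The count of lower genes went to 7 and 20 without replicates 3 and 4 of wild type PBS, and to 8 without replicate 3, 5 or 6 of knockout PBS. Without replicates 1 and 2 of wild type LPS, a choice made after the data were seen, 15 were higher and 21 lower. Camera called 6 lists higher and 2 lower, of which 2 held with an estimated correlation. The NADPH oxidase list (adjusted p = 3.04e-08) rested on Cybb, with an adjusted p of 0.116 and the opposite direction without it. The immediate early and glucocorticoid response lists (adjusted p = 0.396 and adjusted p = 0.207 with an estimated correlation) and the circadian list (adjusted p = 0.059) were among those lost, with choroid plexus, meninges and striatum (adjusted p = 0.419, adjusted p = 0.435 and adjusted p = 0.396).

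Between genotypes under LPS, genes of the vessel wall and of complement were lower in the libraries labelled knockout. Vwf differed by -0.70 ± 0.09 on the log2 scale (adjusted p = 1.33e-06), the endothelial adhesion molecule Esam by -0.51 ± 0.08 and the glucose transporter Slc2a1 by -0.30 ± 0.06. C4b differed by -0.47 ± 0.09, C1qa by -0.35 ± 0.07, the lysosomal protease Ctsd by -0.31 ± 0.06 and lysozyme, Lyz2, by -0.67 ± 0.12, and Cd5l was lower by 1.66 ± 0.32. For each of these genes, all 6 knockout LPS libraries lay below the wild type LPS mean, which the naming rule required of Cd5l only. Tmem181b-ps was at least 93.3-fold higher with 3 counts over the group as floor.

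Endothelial identity and barrier genes had 6 of 19 lower and 0 higher (12 and 0 over the list alone), with a median of -0.302 (camera adjusted p = 5.52e-11, adjusted p = 0.0024 with an estimated correlation). Endothelial activation genes had 2 of 16 lower (7 over the list alone, adjusted p = 0.00279 with an estimated correlation). Complement and phagocytosis genes had 4 of 25 lower and 0 higher (16 and 0 over the list alone), with a median of -0.347 (camera adjusted p = 1.12e-13, adjusted p = 0.00421 with an estimated correlation). Lysosome genes had 2 of 18 lower, activated microglia genes 1 of 21, shared astrocyte reactivity genes 2 of 11, A1 genes 2 of 11 and antioxidant genes 3 of 21 (8, 10, 7, 5 and 6 over the list alone). With an estimated correlation these had an adjusted p of 0.027, 0.0231, 0.027, 0.0302 and 0.0344. Fbln5 of the A1 list was lower by 0.60 ± 0.13 and Prdx6 of the antioxidant list by 0.27 ± 0.06. With an estimated correlation 10 list calls were lost, monocyte and border macrophage genes at an adjusted p of 0.067, neutrophil genes at an adjusted p of 0.24, homeostatic microglia genes at an adjusted p of 0.262 and choroid plexus genes, with Ttr (transthyretin) higher by 0.33 ± 0.07, at an adjusted p of 0.322. The remaining 6 had an adjusted p from 0.219 for cytokines and chemokines to 0.457 for mitochondrially encoded genes. The NADPH oxidase list, with Rac2 at -0.72 ± 0.18 and Cybb at 1.52 ± 0.11, was not called (camera adjusted p = 0.424). Of its 8 tested genes 1 was higher and 1 lower (1 and 3 over the list alone). Without Cybb, a choice made after the data were seen, it was lower (adjusted p = 0.0216). The synapse list had 0 of 33 called (camera adjusted p = 0.823).

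Several genes under LPS differed as they did under PBS. Wdfy1 stood at -1.76 ± 0.08, Gabra2 at -1.18 ± 0.07 and Ndn at -0.70 ± 0.05, the latter 2 named here after their values were seen, and Ddx3y at 0.70 ± 0.07. S100a5 had 2 counts in the knockout LPS libraries and 134 in wild type LPS, a ratio of 67.5 (exact 95% interval 18.3 to 563), and Cdhr1, a cadherin of mitral cells, stood at -1.74 ± 0.36. With the bulb score as covariate, S100a5 at -4.00 (adjusted p = 0.0788) and Cdhr1 at -0.84 (adjusted p = 0.404) were no longer called, and 21 of the 151 calls under LPS were kept. All 151 kept their sign, and the median absolute log2 fold change went from 0.431 to 0.383 and the median SE from 0.0945 to 0.107. Vwf stayed called at -0.76, as did Slc2a1 at -0.36 and Fbln5 at -0.72. C1qa at -0.24 (adjusted p = 0.297), C4b at -0.44 (adjusted p = 0.149), Lyz2 at -0.50 (adjusted p = 0.21), Cd5l at -1.24 (adjusted p = 0.424), Esam at -0.38 (adjusted p = 0.0718), Ctsd at -0.27 (adjusted p = 0.074), Prdx6 at -0.19 (adjusted p = 0.269) and Ttr at 0.28 (adjusted p = 0.176) did not.

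In total, 38 genes were called higher and 113 lower under LPS, and 53 of these 151 calls were made each time that any of the 12 libraries was left out. Without replicates 1, 2, 3, 4 and 6 of wild type LPS the counts of higher genes were 66, 74, 25, 19 and 24 and those of lower genes 200, 215, 69, 53 and 74. Without replicate 3 of knockout LPS they were 25 and 72, without replicate 2 the lower count was 67, and without replicate 4 the higher count was 23. Without replicates 1 and 2 of wild type LPS together, a choice made after the data were seen, the counts were 177 and 384. The genes named by the rule also included Omp (-2.95 ± 0.75), Sp8 (-1.69 ± 0.42), Glipr1 (-1.29 ± 0.29), Fgr (-1.19 ± 0.30), Snx22 (1.09 ± 0.28), Col11a1 (0.64 ± 0.15) and Amy1 (0.57 ± 0.15). These calls ended in 10, 7, 2, 9, 8, 3 and 9 of the 12 fits with a library left out, and that of Rac2 in 7. The highest adjusted p was 0.104 for Omp and Sp8, 0.0575 for Glipr1 and 0.141 for Fgr, all without replicate 3 of wild type LPS. It was 0.094 for Col11a1 and 0.145 for Amy1 without replicates 4 and 6 of wild type LPS, and 0.111 for Snx22 and 0.103 for Rac2 without replicates 6 and 3 of knockout LPS. Gh at 5.74 ± 1.08 and Pomc at 3.09 ± 0.71 rested on replicate 4 of knockout LPS, with an adjusted p of 0.998 and 0.949 without it.

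The interaction asks for which genes the LPS change differed between genotypes. With all 24 libraries Cybb was the only gene called, with an LPS change lower by 3.90 ± 0.25 on the log2 scale in the libraries labelled knockout (adjusted p = 2.34e-15). Other genes that differed between genotypes under LPS did not pass this test. Ctsd stood at -0.40 ± 0.08 (adjusted p = 0.053), Esam at -0.43 ± 0.13 (adjusted p = 0.276) and Vwf at -0.28 ± 0.20 (adjusted p = 0.676).

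Camera called 11 lists for the interaction, 2 higher (glucocorticoid response and mitochondrially encoded genes) and 9 lower, and none held with an estimated correlation, where each adjusted p lay between 0.185 and 0.532. With the preset correlation alone, lysosome and activated microglia genes had a smaller LPS rise in the libraries labelled knockout (adjusted p = 3.77e-05 and adjusted p = 0.000176), as did the complement, shared astrocyte reactivity, endothelial identity, antioxidant and neutrophil lists. The immediate early list had a lower LPS change, with no rise called in wild type. The call of the NADPH oxidase list rested on Cybb, with an adjusted p of 0.816 and the opposite direction without it. Over all genes, edgeR called 0 genes higher and 1 lower, with 1407 at an unadjusted p below 0.05, and DESeq2 called 0 and 2. Without replicate 1 of wild type LPS, edgeR called 5 higher and 15 lower, and without replicate 2 it called 1 and 6. Without both, a choice made after the data were seen, it called 84 higher and 165 lower. The count of 1 called gene thus moved most without these 2 libraries, which differed from replicates 3 to 6 of their group. They were picked for that difference and had the lowest Cybb levels of their group, so the larger counts without them test nothing. With all 24 libraries kept the count also moved, to 28 higher and 39 lower with no filter and to 3 and 5 with the replicate block. With other single libraries left out, edgeR called 2 lower without replicate 3 or 5 of wild type PBS. It called 4 lower without replicate 3 of wild type LPS or replicate 1 of knockout PBS. It called 3 lower without replicate 4 of knockout PBS or of knockout LPS. It called 1 higher without replicate 5 of wild type PBS, replicates 2, 3 or 4 of knockout PBS, or replicates 1 or 4 of knockout LPS.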

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

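The first draw of splits described here was fixed before the results were seen, and a second draw was made after the first was known. A library stands out here where its gap to the nearest other library, divided by the range of its group, passes Dixon's 95% critical value for 6 samples. Of 358 groups of 6 values, from 98 named genes and the measures of library quality, 27 passed. Chance alone passes about 1 in 20 where values are normally distributed, which low counts are not. Where only 1 library of a group lies above 0 counts, the gap equals the range and that library passes by construction.

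Values are in log2 CPM. Among genes changed by LPS, Ccl5 in replicate 2 of knockout LPS stood at 2.85 (4.35 to 5.14 in the other libraries of the group) and Ccr2 in replicate 1 of wild type LPS at 1.31 (2.44 to 3.01). In wild type PBS, Cx3cr1 and Ifitm3 were high in replicate 1 (6.22 and 4.32), Cd52 low in replicate 3 (1.15), and Serpina3n and Snap25 low in replicate 6 (1.64 and 10.8). Esam was high in replicate 5 of knockout LPS (5.98), and Hbb-bt and Gkn3 in its replicate 6 (4.07 and 2.02). Gpx3 was low in replicate 1 of knockout PBS (2.29). Myelin-lineage genes were low in replicate 3 of wild type PBS, Cldn11 at 7.4 and Bcas1 at 7.72, and Bcas1 also in replicate 1 of knockout PBS at 7.73. Of the genes that differed by genotype, Wdfy1 stood low in replicate 4 of wild type PBS (5.76) and Gabra2 high in replicate 1 of wild type LPS (6.95). Tmem181b-ps stood low in replicate 6 of knockout PBS (1.98).

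Other values stand out at low counts, where -0.935 marks 0 counts. The only library of its group above 0 counts was, in knockout PBS, replicate 6 for Marco and Cd5l (-0.207 each), replicate 4 for Fcgr4 (-0.0387) and replicate 5 for Cxcl1 (-0.353), and in wild type PBS replicate 3 for Tmem181b-ps (-0.443). S100a5 was at 0 counts in replicate 4 of wild type PBS (-0.935, against 2.99 to 4.28), and Sp8 was low in replicate 2 of wild type LPS (-0.333, against 1.92 to 2.68). The pituitary hormone genes stood out in replicate 4 of knockout LPS, Gh at 10.7 (1.7 to 3.18 in the others) and Pomc at 8.11 (1.31 to 3.41). Pomc also stood out in replicate 1 of wild type LPS, at 3.99.

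The LPS change of Cybb differed between genotypes by -3.9, tested as the interaction in edgeR. Each comparison was also set against splits of the same libraries into groups of the same sizes. Of 100 splits with the real one included, 1 gave as many genes called as LPS in wild type (2596, highest other split 1206) and 1 as many as LPS in knockout (1564 and 250). For genotype under LPS it was 2 (151 genes, highest other split 165) and for genotype under PBS 4. There 1 other split gave 63 genes against the real 19, so structure among the libraries other than genotype can give more calls than genotype. For the interaction, 10 of the 100 splits gave as many calls as the real 1 gene, and 90 of the 99 other splits gave 0. A second draw gave 1, 1, 2, 2 and 4 of 100, with 1555, 666, 19, 185 and 3 genes in the highest other split, in the order LPS in wild type, LPS in knockout, genotype under PBS, genotype under LPS and interaction. The interaction count thus lies near the line of 5 in 100, and chance is not excluded for this count. The splits ask how often any gene is called and do not weigh the Cybb call itself. That call was made each time a library was left out.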

How the results depend on the processing

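Fits without replicates 1 and 2 of wild type LPS, with the olfactory bulb score, without the mitochondrial genes and Gm42418, and the NADPH oxidase list without Cybb were chosen after the data were seen. Of 181 called gene results named in the text, 154 kept their direction and call under every alternative that gave a value for them, and 3 of 198 named results reversed. The named genes were in part picked for such stability, so the calls over all genes are the fairer count. There, 1745 of 2596 calls of LPS in wild type were made each time a library was left out, 1083 of 1564 of LPS in knockout, 13 of 19 of genotype under PBS, 53 of 151 of genotype under LPS and 1 of 1 of the interaction. DESeq2's size factors, plain total counts and the fit without mitochondrial genes and Gm42418 changed the side of the threshold for 0 of the 198. With the bulb score 25 were no longer called, and with the DESeq2 Wald test 6. At the lowest depth 1 CPM stands for 2.34 counts, and no fit varied depth, so what depth limits was not tested.

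The reversed results were Gh in LPS in knockout (-0.43 to 6.07 with a library left out), Pomc there (-0.0736 to 3.37) and Pomc for genotype under LPS (-0.12 to 3.52), each lowest without replicate 4 of knockout LPS. Without Cybb the NADPH oxidase list turned, with an adjusted p of 0.116 for genotype under PBS, 0.0216 under LPS and 0.816 for the interaction. By construction, this shows how far the list rests on the gene left out.

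Counts of calls moved as follows, as higher/lower, and the cause was not tested unless given. An added threshold of log2 1 left 518/14 for LPS in wild type, 427/11 in knockout, 6 lower for genotype under PBS and 9/14 under LPS, by construction. With DESeq2, genotype under PBS had 10 higher and the interaction 2 lower. With no filter, genotype under PBS had 43/45, under LPS 97/196 and the interaction 28/39, and with the stricter filter the interaction had 1/3. With only the libraries compared, genotype under PBS had 16 higher. Without replicates 1 and 2 of wild type LPS, genotype under PBS had 15/21, under LPS 177/384 and the interaction 84/165. With the bulb score, genotype under PBS had 7 lower and under LPS 7/14. With an estimated correlation, 2, 9 and 0 lists were called for genotype under PBS, under LPS and the interaction.

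Leaving out a library gave 1395 to 1658 higher and 800 to 1096 lower for LPS in wild type, 925 to 1057 and 392 to 550 in knockout, 6 to 15 and 7 to 20 for genotype under PBS, 19 to 74 and 53 to 215 under LPS, and 0 to 5 and 1 to 15 for the interaction. The slope between the LPS changes ranged from 0.84 to 0.879.

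The labels number the replicates of each group alike. With the number as replicate block, genotype under PBS had 22 higher, genotype under LPS 71/202 and the interaction 3/5. The numbers hardly correlate across groups (36 correlations from -0.0766 to 0.165, 2 of them over 0.1), and 9 of 24 libraries fit best with their own number. That is a hint from the data and says nothing of the design.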

Other observations

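The tests of mislabelling, of a segment near Cybb, of genetic background, of the loss of Nox2, of S100a5 and of depth were chosen after the results were seen. Predictions for the held-out bulb genes, for the mean LPS change and for its slope with the bulb score were written before those tests were run. They were not fixed before the data were examined. The held-out genes were bulb genes not among the calls, and the bulb score was added after seeing the data.

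Among the genes called in both genotype comparisons were 10 reported here besides Cybb: Tmem181b-ps, Ddx3y, Wdfy1, Gabra2, Ndn, S100a5, Omp, Mt3, Shisa3 and Gm47283. Mt3, Shisa3 and the predicted gene Gm47283 lie outside the rule for named genes and were chosen after their values were seen. For 6 of them the 12 libraries labelled knockout and the 12 labelled wild type did not overlap, and only Mt3 had an unadjusted interaction p below 0.05. A segment carried along with the targeted Cybb locus is argued against, since 0 of the 10 lie within 20 Mb of Cybb. A single library under the wrong label is argued against as well, with 0 libraries whose Cybb level lies within the range of the other label. This asks only whether a library is like the others of its label, and does not check which label is the knockout. An exchange of the labels of whole groups stays open. The 10 genes lie on 7 chromosomes, but genes changed by loss of Nox2 or by tissue content could also lie on several. This count therefore does not favour a different genetic background of the genotypes, which stays open. S100a5, Omp and Shisa3 are also among the olfactory bulb genes gathered below. Loss of Nox2 acting on these genes cannot be told apart from a different background that follows the labels, as both would split the libraries the same way. In 0 libraries was the Wdfy1 level of 1 label combined with the other label. Wdfy1 had already been seen to separate the labels, so this count was fixed in advance and decides nothing.

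Some genes known from the olfactory bulb and nerve were lower in the libraries labelled knockout. The first 14 such genes were gathered after their values were seen, mostly from the calls, so they test nothing. Of 11 tested genes held out for the test, 10 were lower under LPS with a median of -0.333 and 9 under PBS with a median of -0.244, and 0 were called. Barhl2 and Trh, which also stand in lists fixed earlier, had been seen there. This could come from less bulb tissue in those hemispheres, a test that could have come out the other way. Regulation by genotype without a change of tissue stays open. S100a5 varied widely within the wild type, with 3 of 12 libraries at 0 counts and the other 9 at 26 to 83. The highest level in wild type LPS was at least 9.39 times that of replicate 1, taken at 3 counts in place of its 0. S100a5 is among the genes that raised the question, so these values decide nothing.

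On average, the LPS changes were smaller in the libraries labelled knockout. This did not hold for every gene or list, and Cybb alone was called for the interaction with all 24 libraries. Over 3259 genes called for the average LPS change, the mean change toward the average direction was 0.553 in wild type and 0.451 in knockout, a difference of 0.102 (two-sided permutation p = 0.00609, 1e+05 draws, labels exchanged within each injection). This p argues against a chance difference between animals only where they vary independently, since the permutation treats the libraries of an injection as exchangeable. The wild type LPS libraries did not all resemble each other equally, as described above. Structure shared by some libraries of a group, other than genotype, was not tested and stays open. With the bulb score as covariate the slope was 0.852, against 0.859 without it, so what this score tracks did not account for the smaller changes. The score did not take up the whole bulb difference, as S100a5 still stood at -2.71 under PBS and -4.00 under LPS. The held-out bulb genes were also lower after both injections, which largely cancels in an LPS change. Bulb tissue as a cause therefore stays open. The LPS groups differed by 0.0112 in mean depth (in units of 1e+06 counts), which argues against depth. Loss of Nox2 and a different genetic background that follows the labels cannot be told apart here, as both would split the libraries the same way. The Wdfy1 level and the genotype label differ in 0 libraries, which was known before and decides nothing.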
